A study of Mus musculus with 2 samples.

How the data were processed

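T cells from the meninges, the membranes around the brain, of untreated C57BL/6 mice aged 7 months were measured by single-cell RNA sequencing with the 10x Genomics 5' kit. Per the labels' protocols, flow cytometry was used to isolate 3 populations, namely mucosal-associated invariant T (MAIT) cells and the CD4 and CD8 lineages. They were combined at a ratio of 1 to 4 to 4, and that mixture was split at random into 2 libraries. The libraries are therefore technical parts of 1 pool, and the number of animals is not given in the sources used here. With 1 pool there is no test across samples and no p-value is given. By the labels the spread between the libraries is technical, though whether both held the same mixture was not settled.

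The deposited matrices hold raw counts of unique molecular identifiers (UMIs) per gene and cell barcode for 31053 genes, per the file headers and the whole-number values. Per the submitters' processing notes, reads were processed with Cell Ranger 5.1.0, STAR and the mm10 mouse genome; the matrix header names software version 3.1.0 instead, and which release made the files was not settled. The gene annotation release is not given in the sources used here. The sort label of each cell is not recorded in the files used here, so cell classes were rebuilt from expression. No receptor (V(D)J) sequences were analysed here.

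Library 1 held 401 barcodes and 1202401 UMIs, with a median of 2704 UMIs per barcode. Library 2 held 215 barcodes and 660814 UMIs, with a median of 2805. No barcode was shared between them. Cells with at least 200 genes and under 10% mitochondrial UMIs were kept, which removed 1 barcode and 6 barcodes, and doublets were called per library with Scrublet as run in scanpy 1.11.5. It marked 45 and 42 barcodes, together 14.1%, a high rate for so few cells, so results with these barcodes kept are among the alternatives. The kept set was 351 cells of library 1 and 171 cells of library 2.

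Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 20 principal components, 15 neighbours and Leiden clustering at resolution 1.0 gave 8 clusters. Members of the gene lists and receptor and immunoglobulin segment genes were left out of the variable genes, so that the clusters were not made from the list genes they are compared on. Clusters were named from markers fixed before the data were examined. The scoring rule was set after the marker scores of the clusters under several settings had been seen: the mean log2 marker ratio to the other cells, with 50 CPM added, had to reach 0.5, lead every other marker list by 0.5 and rest on at least 3 detected markers. That rule left 2 T-cell clusters without a name. The markers also cover gamma delta T cells, invariant natural killer T cells, natural killer and innate lymphoid cells, macrophages, antigen-presenting cells, B cells, neutrophils, fibroblasts, endothelial cells, erythroid cells and cycling cells.

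UMIs were summed per class and expressed as CPM, the UMIs of a gene per 1000000 UMIs of the class, over both libraries and in each. Ratios of summed counts carry exact 95% intervals (conditional binomial), CPM values exact Poisson intervals and shares of cells exact Clopper-Pearson intervals. All cover counting error only, not differences between animals, cells or libraries. Log2 folds add a pseudocount of 1 UMI per class sum. Where a class had no UMI of a gene, the fold is a bound computed with 3 counts over the class in place of 0, and the limit given for a share of 0 is likewise 3 cells of the total; both are floors of counting, not the exact intervals. A gene was called higher or lower by a rule of size, not a test: at least 1.5-fold over both libraries, the same direction in each, and at least 10 UMIs in the higher class. A list's median was taken over members with at least 10 UMIs in the classes compared, and set among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The gene Aldoa maps to 2 identifiers and was left out of the glycolysis list.

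The text names up to 4 members per list and comparison, those with the largest log2 fold past the rule of size, with Selenop, Fth1, Ftl1, Gpx1, Gpx4, Prdx1 and Sod1 always given. For genes outside the lists, cells of the T-cell clusters were grouped again by gates, whatever their class. The MAIT gate needed a Trav1 UMI. The CD4 gate needed a Cd4 UMI and the CD8 gate a Cd8a or Cd8b1 UMI, each without the other's and without Trav1 or Zbtb16. The 10 genes with the highest and 5 with the lowest smaller fold over both gates were named, among genes with at least 30 UMIs, a fold of at least 2 against both gates, the same direction in each library and UMIs in at least 10% of cells of the higher gate. Marker, receptor, ribosomal and mitochondrial genes were left out. Some genes that these rules select are not described in the text, though they are counted. Leading genes of clusters are given as identity only. The 13 gene lists, the gates and these rules were fixed before the data were examined; the score at which a cluster counted as non-T was set afterwards.

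The calculation was tested on simulated class sums drawn from the real totals, with 200 genes raised. For MAIT-like over CD4-like cells, over 5888 genes, 55% of genes raised 2-fold and 95% of those raised 4-fold were called. Of 5688 unchanged genes, 15.9% met the rule by counting noise, falling to 3.48% of the 689 with at least 100 UMIs. For MAIT-like over CD8-like cells, over 6129 genes, the values were 54% and 98%, with 14.9% of 5929 unchanged genes and 2.21% of 768. The 95% intervals held the true ratio for 96.9% and 97.2% of genes. The simulated counts had no variation between cells or libraries, as the intervals assume, so this coverage checks the calculation only. Real counts varied more: Ccl5 in CD4-like cells was at 3507 CPM (3276 to 3750) in library 1 and 457 CPM (329 to 617) in library 2. The share of unchanged genes that meet the rule may therefore be higher in the real data.

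Alternatives were a stricter cell filter (500 genes, 5% mitochondrial), called doublets kept, resolutions 0.5 and 2.0, list members included in the clustering, gates in place of clusters, a stricter MAIT gate that also needs Zbtb16, TMM scaling (edgeR 4.0.16), UMIs thinned to 1000 per cell, cells with a macrophage UMI left out, each library left out, other minimums of UMIs and a pseudocount of 5. The depth of 1000 UMIs and the limit of 1 log2 unit for calling a gene's fold moved were set after the data were examined. So were 4 added alternatives: libraries weighted equally, unnamed T-cell clusters added to the class with the highest marker score, the cell with the most UMIs of a gene left out, and counts of list members per library, under TMM scaling and by gate. Gene positions are from GENCODE vM21 on GRCm38 (mm10), matched on gene identifier for 98 of 98 named genes. Software was Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and R 4.3.3.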

Results

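Single-cell transcriptomes of meningeal T cells were collected from untreated C57BL/6 mice aged 7 months. MAIT cells, which carry a semi-invariant T-cell receptor built with the Trav1 segment, were mixed with CD4 and CD8 T cells, and the 2 libraries made from that mixture were examined for how MAIT cells differ from either lineage. Library 1 held 401 barcodes and 1202401 UMIs and library 2 held 215 barcodes and 660814 UMIs, of which 351 and 171 cells were kept. Because both libraries came from 1 pool, every value describes that pool, intervals cover counting error only, and no difference between animals was tested.

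Clustering separated 73 MAIT-like, 141 CD4-like and 139 CD8-like cells, with median depths of 3208, 2377 and 2914 UMIs. Trav1, which was left out of the clustering but is among the markers that gave the class its name, had a UMI in 27.4% of MAIT-like cells (95% interval 17.6 to 39.1), in 3.60% of CD8-like cells (1.18 to 8.20) and in 0 of 141 CD4-like cells, which allows a share of up to 2.13%. Cd4 was detected in 31.2% of CD4-like and 2.74% of MAIT-like cells, and Cd8a in 77.7% of CD8-like and 10.96% of MAIT-like cells. Cd40lg, fixed as a CD4 marker, was detected in 63.0% of MAIT-like and 35.5% of CD4-like cells. Of the markers of other lineages, Trdc of gamma delta T cells had no UMI in MAIT-like cells while Tcrg-C1 had a UMI in 21.9% of them, and any of the macrophage genes C1qa, C1qb, C1qc, Lyz2, Pf4 and Mrc1 had a UMI in 3 MAIT-like cells, 0 CD4-like cells and 1 CD8-like cell. Of the other macrophage markers, Apoe had a UMI in 2 MAIT-like cells and Ms4a7 in 1, and neither had any in CD4-like or CD8-like cells. Cd68 had a UMI in 1 CD4-like and 1 CD8-like cell, and Csf1r, Aif1 and Cd14 had none in these classes. The Trav11 and Traj18 segments of invariant natural killer T cells had no UMI in any cell, nor did Traj33, so the joining segment of MAIT receptors could not be read from these data. Another 113 cells of T-cell clusters 4 and 6 and 56 cells of clusters 3 and 7 were left unnamed.

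The classes were unevenly divided between the libraries. MAIT-like cells made up 5.70% of kept cells in library 1 (3.51 to 8.66) and 31.0% in library 2 (24.2 to 38.5). CD8-like cells made up 31.1% (26.2 to 36.2) and 17.5% (12.2 to 24.1), and CD4-like cells 27.6% and 25.7%. Among cells of the 3 named classes, MAIT-like cells were 8.85% in library 1 and 41.7% in library 2, against 11.1% in the mixture given by the labels. Library 2 gave 72.6% of MAIT-like cells, so class and library overlap in part. Of 97 pooled gene folds past the rule of size, 61 differed by over 1.5 times from the fold within at least 1 library, with a mean of 1 UMI added per class to avoid division by 0. Some of these folds within the libraries are given below as log2 values.

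**Figure D1:**
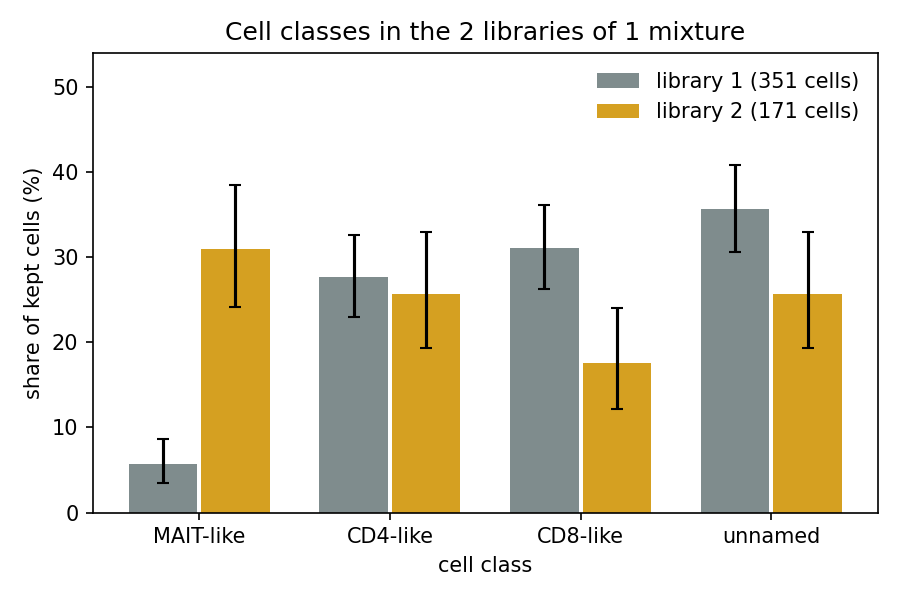
Share of kept cells, in percent, in each class for library 1 (351 cells, grey) and library 2 (171 cells, yellow); bars give the share and error bars the exact 95% interval. The MAIT-like share was 5.70% in library 1 and 31.0% in library 2, with intervals that do not overlap.

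Against CD4-like cells, MAIT-like cells had more transcripts of the type 17 genes Tmem176a and Tmem176b, of the innate-like T cell genes S100a4, Cxcr6 and Ccr2, of Selenop and Gpx1, and of immediate early genes. They had fewer transcripts of naive and recirculating T cell genes such as Ccr7 and S1pr1, and of Areg, Tnfrsf4 and Ifi27l2a. Against CD8-like cells the same type 17, innate-like and antioxidant genes were higher, and the cytotoxic genes Gzma, Gzmm and Klrd1 and the chemokine gene Ccl5 were lower. Oxidative phosphorylation genes differed little in either comparison, with medians of 0.11 and 0.026 on the log2 scale.

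Selenop, the gene of the secreted selenium carrier selenoprotein P, was 6.37-fold higher in MAIT-like than in CD4-like cells (4.38 to 9.49; 148 and 35 UMIs) and 15.2-fold higher than in CD8-like cells (9.29 to 26.4; 18 UMIs). It was detected in 71.2% of MAIT-like, 17.7% of CD4-like and 12.2% of CD8-like cells, and after thinning to 1000 UMIs in 53.7%, 7.76% and 2.38%. Within library 1 the log2 folds were 2.83 and 3.72 and within library 2 they were 2.00 and 3.58. Gpx1, a glutathione peroxidase, was 3.95-fold (3.07 to 5.11) and 6.91-fold (5.19 to 9.33) higher, and the peroxiredoxin gene Prdx6 1.91-fold (1.49 to 2.44) and 2.42-fold (1.889 to 3.104) higher. Over CD4-like cells Gpx1 was at 1.33 log2 within library 1 and 2.21 within library 2. The ferritin heavy chain gene Fth1 was 1.75-fold higher than in CD8-like cells (1.58 to 1.94), and its ratio to CD4-like cells was 1.45 (1.31 to 1.61), below the rule of size. With gates its ratios were 1.39 to the CD8 gate (1.196 to 1.609) and 1.345 to the CD4 gate (1.131 to 1.596), both below that rule. Ftl1 had ratios of 1.11 and 1.31, Gpx4 0.789 and 0.943, Prdx1 0.924 and 1.16, and Sod1, with 7 UMIs in MAIT-like cells, 0.879 and 1.08. Selenop (ENSMUSG00000064373) lies on chromosome 15 (3268547 to 3280508, plus strand), Gpx1 (ENSMUSG00000063856) on chromosome 9 (108338903 to 108340343, plus strand), Prdx6 (ENSMUSG00000026701) on chromosome 1 (161240112 to 161251219, minus strand) and Fth1 (ENSMUSG00000024661) on chromosome 19 (9980598 to 9985098, plus strand), all protein-coding genes of mm10.

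Over the whole antioxidant and iron storage list, 6 of 25 measured members were higher and 2 lower than in CD4-like cells, and 6 of 26 were higher and 0 lower than in CD8-like cells. Counted in library 1 alone, 4 of 23 were higher and 3 lower than in CD4-like cells and 5 of 25 higher and 4 lower than in CD8-like cells. In library 2 alone the counts were 10 of 24 and 1, and 8 of 23 and 0. Glrx, a glutaredoxin gene, was lower, by 2.42-fold against CD4-like cells (1.40 to 4.42), and Cat, the catalase gene, had 12 UMIs in MAIT-like cells and a ratio of 2.47 to CD8-like cells with an interval from 0.954 to 6.63. The list medians were 0.21 and 0.20 log2, at the 83.9 and 80.9 percentiles of matched random lists, so the list as a whole did not stand apart. The medians were 0.13 and 0.31 within library 1 and 0.39 and 0.39 within library 2. In simulation 15.9% and 14.9% of unchanged genes met the rule of size by counting noise, so a few members past it say little, and TMM scaling lowered the medians to 0.10 and 0.028. It lowered the median of all measured genes from 0.068 to −0.040 over CD4-like and from 0.099 to −0.060 over CD8-like cells, about the same shift.

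**Figure D2:**
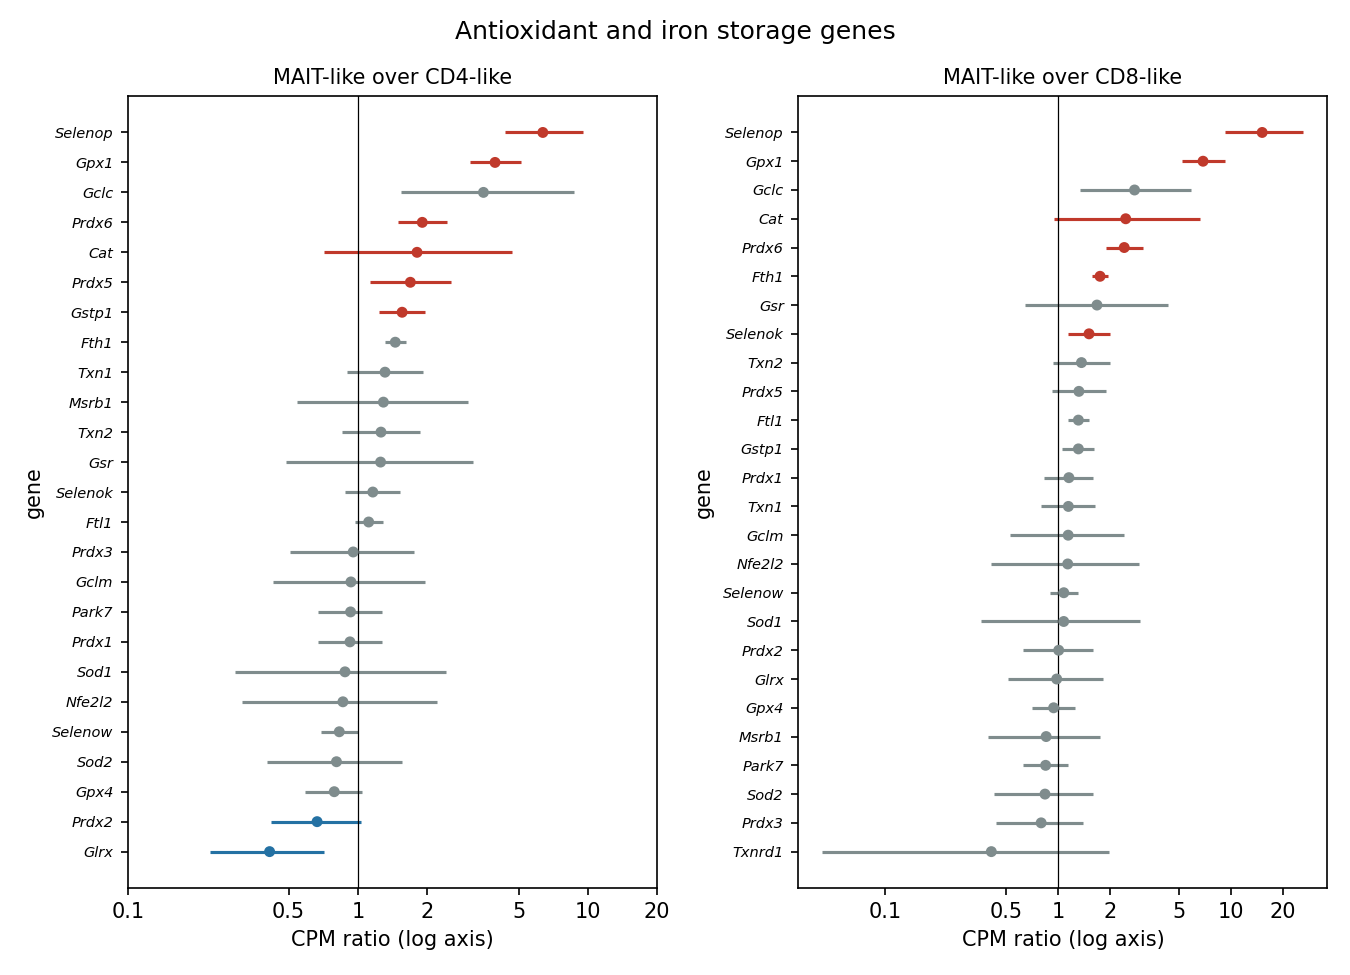
Ratio of CPM in MAIT-like cells to CD4-like cells (left) and CD8-like cells (right) on a log axis, for each measured antioxidant and iron storage gene over both libraries; lines are exact 95% counting intervals, red marks genes higher and blue genes lower by the rule of size, grey neither. Selenop is the highest gene in both panels, at 6.37 and 15.2, and Gpx1 follows at 3.95 and 6.91.

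Type 17 genes were higher in MAIT-like cells than in CD4-like cells for 11 of 14 measured members and than in CD8-like cells for 11 of 14, with none lower. The ion channel genes Tmem176a and Tmem176b were 64.3-fold (29.1 to 177) and 51.4-fold (26.7 to 114) above CD4-like cells, and Tmem176a at least 158-fold above CD8-like cells, which had no UMI of it. Actn2, which encodes an actinin, had 97 UMIs in MAIT-like and 1 in CD4-like cells. Over CD4-like cells, Tmem176a was at 5.765 and 4.89 log2 within libraries 1 and 2 and Actn2 at 4.70 and 6.01. Ltb4r1, a leukotriene receptor gene, was at least 38.2-fold above CD8-like cells. The list medians were 4.53 and 4.84 log2, both above all 10000 random lists, and 3.75 and 4.68 within library 1 and 3.06 and 3.75 within library 2. With gates they were 2.63 and 4.10, with 8 of 11 and 9 of 10 members higher, and with a pseudocount of 5 UMIs 2.81 and 3.30. Il17a, the cytokine gene, had 97 UMIs in MAIT-like cells, 1 in CD4-like cells and 0 in CD8-like cells, but 65 of the 97 came from a single cell of library 1 that also held 3 Cd4 UMIs and no Trav1 UMI. Over CD4-like cells Il17a was at 7.87 log2 within library 1 and 2.09 within library 2. Only 2 MAIT-like cells held a Cd4 UMI, that single cell among them, and both fell in the CD4 gate. The 65 Il17a UMIs of the CD4 gate were therefore all from that 1 MAIT-like cell. With it placed there, the Il17a fold of the MAIT gate over the CD4 gate was −1.33 log2 over both libraries. Within library 1 this fold was −0.57 and within library 2 it was 1.53. Il17a had a UMI in 13.7% of MAIT-like cells.

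Type 1 and cytotoxic genes were lower than in CD8-like cells for 15 of 18 measured members, with none higher and a median of −2.85 log2 (−1.70 and −3.004 within the libraries). With gates 10 of 19 were lower and the median was −1.30. Ccl5, a chemokine gene, was 65.3-fold lower (49.6 to 87.8), the granzyme gene Gzma 73.0-fold lower (12.9 to 2904), the granzyme gene Gzmm at least 4.87-fold lower, and the killer receptor gene Klrd1 25.1-fold lower (6.77 to 211). In CD8-like cells Gzma had a UMI in 10.1% of cells, with 23.7% of its UMIs in 1 cell, and Gzmm in 5.76%. Within libraries 1 and 2 the log2 folds were −4.35 and −7.66 for Ccl5, −3.59 and −6.065 for Gzma and −3.225 and −4.32 for Klrd1. Against CD4-like cells 5 of 14 were lower and 3 higher. There Ccl5 was 11.7-fold lower (8.82 to 15.8), Klrg1 9.29-fold (1.41 to 393) and the chemokine gene Ccl4 4.98-fold (2.12 to 14.3), while Klrk1, the NKG2D gene, was 24.1-fold higher (3.74 to 1011). The pooled median of −0.55 over CD4-like cells was not found within the libraries, where it was 0.0078 and −0.13, and it turned to 0.56 with gates, where 2 of 12 members were higher and 1 lower. Ccl5 was at −2.29 and −2.56 log2 within libraries 1 and 2, both smaller in size than the pooled −3.53, and its level in CD4-like cells was 3507 CPM in library 1 and 457 CPM in library 2. Ccl4 was at −0.80 and −2.19, Klrg1 at −2.95 and −1.57 and Klrk1 at 2.51 and 3.465. With gates Ccl5 over the CD4 gate was at 0.057 log2 over both libraries, from 2.01 within library 1 and −5.81 within library 2. Over the CD8 gate its ratio was 0.216 (0.190 to 0.244), at −0.72 log2 within library 1 and −7.36 within library 2. The MAIT gate held 265 Ccl5 UMIs, against 39 and 12 in all MAIT-like cells of libraries 1 and 2. Most of the 265 therefore lay in gated cells outside the MAIT-like class, and the gate held 5 CD8-like cells and 1 unnamed cell. Of the Ccl5 UMIs of MAIT-like cells, 62.7% came from 1 cell.

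Innate-like T cell genes were higher than in CD4-like cells for 13 of 16 measured members and than in CD8-like cells for 11 of 17, where 1 was lower. S100a4, a calcium-binding protein gene, was 5.94-fold (4.55 to 7.84) and 6.63-fold (5.13 to 8.65) higher. The chemokine receptor genes Cxcr6 and Ccr2 were 4.13-fold (3.18 to 5.43) and 5.23-fold (3.01 to 9.57) above CD4-like cells, and Il18rap, an interleukin 18 receptor gene, 6.40-fold (2.09 to 26.2). Over CD4-like cells the folds within libraries 1 and 2 were 1.87 and 3.67 log2 for S100a4, 2.72 and 1.28 for Cxcr6 and 1.53 and 3.98 for Ccr2. The costimulatory gene Icos was at 654 CPM against 72.7 CPM in CD8-like cells and the transcription factor gene Maf was 6.81-fold above them (4.33 to 11.1). Icos was at 3.12 and 3.82 log2 within the libraries and Maf at 2.12 and 3.01. The medians were 1.66 and 1.13 log2, with 1.20 and 1.23 within library 1 and 1.58 and 1.11 within library 2. Naive and recirculating T cell genes were lower for 9 of 11 members against CD4-like cells, with none higher, and for 6 of 8 against CD8-like cells, with 1 higher. S1pr1, needed for exit from lymph nodes, was 14.6-fold below CD4-like cells (6.07 to 45.9), Actn1 at least 4.43-fold, and Ccr7 17.3-fold (2.84 to 708) and 6.49-fold (0.96 to 277) below the classes. The transcription factor gene Klf2 was 3.95-fold below CD8-like cells (2.03 to 8.58), and Satb1 was 3.08-fold above them (1.01 to 10.3) on 10 UMIs but at −3.19 log2 with gates. Within libraries 1 and 2, S1pr1 was at −3.19 and −4.295 log2 over CD4-like cells, and Klf2 at −1.23 and −2.83 and Satb1 at 2.25 and 0.89 over CD8-like cells. Against CD8-like cells 4 of 6 naive members were lower in library 1 alone and 2 of 3 in library 2 alone. The naive medians were −2.33 and −1.39 log2, with −2.70 and −1.74 within library 1 and −2.57 and −1.04 within library 2.

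Tissue residency genes went both ways, with 3 of 10 higher and 3 lower against CD4-like cells and 5 of 10 higher and 1 lower against CD8-like cells. The transcription factor gene Bhlhe40 was 2.76-fold (2.05 to 3.74) and 3.94-fold (2.89 to 5.43) higher and the activation and retention gene Cd69 2.499-fold (1.67 to 3.78) and 3.70-fold (2.42 to 5.76) higher. Nr4a1 was 3.82-fold above CD8-like cells (2.65 to 5.58). Nr4a2 was 2.75-fold (1.18 to 7.44) and 5.87-fold (2.72 to 15.1) lower, and Prdm1 at least 2.21-fold below CD4-like cells. Over CD4-like cells Nr4a2 was at −0.0088 log2 within library 1 and −2.32 within library 2 and turned to 0.54 with gates. Over CD8-like cells it was at −0.97 and −3.72, and Nr4a1 at 0.66 and 1.42. The counts were 2 of 8 higher and 1 lower, and 2 of 9 and 1, in library 1 alone, and 4 of 8 and 2, and 4 of 7 and 1, in library 2 alone. Medians were 0.29 and 0.67 log2, with −0.0090 and 0.34 within library 1 and 0.78 and 1.32 within library 2.

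Regulatory T cell genes were split against CD4-like cells, with 2 of 6 higher and 3 lower, and 4 of 6 were higher than in CD8-like cells. Foxp3, a CD4 marker not on this list, had a UMI in 0 MAIT-like and 0 CD8-like cells and in 11.3% of CD4-like cells. The list members Ikzf4, Il10, Itgb8 and Lrrc32 also had no UMI in MAIT-like or CD8-like cells, so the comparison with CD8-like cells does not cover them. The actin-capping gene Capg was 3.74-fold (2.95 to 4.79) and 17.1-fold (11.4 to 26.8) higher and Il2ra, the interleukin 2 receptor alpha chain gene, 3.64-fold (1.80 to 7.83) and 26.8-fold (6.78 to 232) higher. The costimulatory receptor genes Tnfrsf4 and Tnfrsf18 were 62.4-fold (17.03 to 519) and 3.68-fold (2.32 to 6.09) below CD4-like cells, and Tnfrsf9 and Ikzf2 were 7.40-fold (2.00 to 40.9) and 2.63-fold (1.408 to 5.001) above CD8-like cells. Tnfrsf9 had UMIs in 3 MAIT-like cells, 1 of which held 75% of them, and was at −0.056 log2 with the stricter cell filter. Within libraries 1 and 2 it was at 1.065 and 1.85 log2 over CD8-like cells, Capg at 3.43 and 4.115 and Il2ra at 3.11 and 4.23. Over CD4-like cells Capg was at 1.29 and 2.10, Tnfrsf18 at −2.59 and −1.61 and Tnfrsf4 at −6.29 and −5.13. Over the CD4 gate Capg was at 0.17 log2 within library 1 and 3.43 within library 2. In library 1 alone 1 of 3 regulatory members was higher and 1 lower than in CD8-like cells. The medians were −0.56 and 1.89 log2, with −1.55 and 0.94 within library 1 and −0.21 and 1.34 within library 2, and the first turned to 0.80 with gates. Of tissue repair factors, 2 of 7 were higher and 2 lower against CD4-like cells and 4 of 8 higher against CD8-like cells. Tnf, a cytokine gene, was 7.59-fold (4.95 to 12.1) and 6.92-fold (4.74 to 10.4) higher and the protease gene Furin 6.46-fold (2.78 to 17.4) and 11.1-fold (4.26 to 36.6) higher. Areg, the amphiregulin gene, was 31.0-fold below CD4-like cells (10.4 to 152) and Hif1a 5.61-fold (2.80 to 12.7). Most Areg UMIs of the CD4-like class, 129, lay in CD4-like cluster 1, in 37.5% of its cells. A single cell held 27.1% of the Areg UMIs of the class. Csf2 was at least 14.2-fold above CD8-like cells, and Tgfb1 1.68-fold (1.12 to 2.51), which fell below the rule of size with TMM scaling. Furin was at 1.85 and 2.41 log2 over CD4-like and 2.76 and 2.265 over CD8-like cells within libraries 1 and 2, and Areg at −6.00 and −4.01 over CD4-like cells. Over the CD4 gate Furin was at −0.16 log2 within library 1 and 2.67 within library 2. A single cell held 33.3% of the Furin UMIs of MAIT-like cells. Repair members higher than in CD8-like cells numbered 2 of 4 in library 1 alone and 3 of 5 in library 2 alone. The medians were 0.28 and 0.49 log2, with 0.36 and 0.66 within library 1 and −0.24 and 0.43 within library 2, and the first was −0.060 with called doublets kept.

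Inhibitory receptor and exhaustion genes were lower for 6 of 8 members against CD4-like cells and for 4 of 7 against CD8-like cells, with 1 higher in each. The checkpoint receptor gene Tigit had 1 UMI in MAIT-like cells and was 29.9-fold (5.09 to 1206) and 26.0-fold (4.44 to 1046) lower, and Pdcd1, the gene of PD-1, 4.56-fold (2.16 to 11.1) and 2.70-fold (1.25 to 6.69) lower. Cd200 was 27.2-fold (4.62 to 1101) and Lag3 at least 3.32-fold below CD4-like cells, Cd160 was 3.40-fold below CD8-like cells (1.52 to 8.94) but at 0.28 log2 with gates, and the ectonucleotidase gene Nt5e was 7.40-fold above them (2.69 to 25.2). Over CD4-like cells 3 of 7 members were lower in library 1 alone, 2 of 3 in library 2 alone and 2 of 5 with gates. Tigit was at −4.80 log2 within library 1 and −0.45 within library 2 there, Cd200 at −4.56 and −1.91 and Pdcd1 at −2.77 and −1.795. Over CD8-like cells Pdcd1 was at −2.24 and −0.48, Cd160 at −0.89 and −2.75 and Nt5e at 1.57 and 3.77. The medians were −1.53 and −1.36 log2, with −1.51 and −0.89 within library 1 and −0.56 and −0.54 within library 2, and the first was −0.12 with gates.

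Immediate early and dissociation genes were higher than in CD4-like cells for 12 of 14 members and than in CD8-like cells for 14 of 14. Fos, Fosb and Jun, which encode parts of the AP-1 transcription factor, are on this list. Fosb was 12.7-fold (6.55 to 27.4) and 31.1-fold (12.8 to 98.2) higher, Jun 7.53-fold (5.269 to 11.03) and 10.1-fold (6.952 to 14.97) higher, and Fos 15.6-fold above CD8-like cells (11.1 to 22.6). Hspa1b, a heat shock gene, was 10.8-fold above CD4-like cells (4.58 to 31.0), and Atf3 at least 8.03-fold and 9.86-fold above the classes. Hspa1b was at 3.19 and 1.91 log2 and Fosb at 2.79 and 3.41 over CD4-like cells within libraries 1 and 2, and over CD8-like cells Fosb was at 3.82 and 4.405 and Jun at 2.58 and 3.16. Over CD4-like cells 7 of 11 members were higher in library 1 alone and 6 of 12 with gates. With gates Fosb was 13.87-fold (4.113 to 72.88) above the CD4 gate and 8.751-fold (4.204 to 18.73) above the CD8 gate. Jun was 4.641-fold (2.875 to 7.68) and 9.11-fold (5.968 to 14.04) above them, and Fos 8.168-fold (5.955 to 11.25) above the CD8 gate. The medians were 1.77 and 2.80 log2, with 1.18 and 2.28 within library 1 and 1.18 and 2.18 within library 2. Grouped by gates they were 1.06 and 1.76. The labels give MAIT cells as a sorted population of their own, and these genes are known to respond to tissue dissociation. Interferon-stimulated genes were lower for 6 of 12 members against CD4-like cells, and against CD8-like cells 4 of 10 were higher and 1 lower. Ifi27l2a was 11.5-fold (8.52 to 15.9) and 3.83-fold (2.80 to 5.36) lower, and against CD4-like cells Ly6a 1.97-fold (1.59 to 2.47), Bst2 1.69-fold (1.20 to 2.41) and Usp18 2.82-fold (0.92 to 11.5). Irf7, an interferon regulator gene, was 2.09-fold (1.32 to 3.30), Ifit1 2.25-fold (1.04 to 4.92) and Ifit3 2.31-fold (1.01 to 5.41) above CD8-like cells. Within libraries 1 and 2 Usp18 was at −0.37 and −1.67 log2 over CD4-like cells, and over CD8-like cells Ifit1 was at 1.59 and 1.73 and Ifit3 at 2.41 and 0.21. With gates Bst2 over CD4 cells turned to 1.08, and Ifit1 and Ifit3 over CD8 cells to −0.51 and −1.03. With the stricter cell filter Usp18 turned to 0.64 and Irf7 to −0.75 in the same comparisons. Against CD4-like cells 3 of 11 members were lower in library 1 alone and 3 of 10 in library 2 alone. The direction of this list depended on how cells were grouped: its median over CD8-like cells was 0.52 log2 (0.58 and 0.57 within the libraries) but −0.73 with called doublets kept and −0.51 with gates, and over CD4-like cells −0.68 (−0.35 and −0.38 within the libraries) but 0.35 with gates.

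Of 21 oxidative phosphorylation genes, Cox5a and Uqcr11, subunits of respiratory complexes, were 1.78-fold (1.34 to 2.38) and 1.72-fold (1.18 to 2.51) above CD4-like cells, and none met the rule of size against CD8-like cells. Over CD4-like cells Cox5a was at 0.53 log2 within library 1 and 1.86 within library 2. Of oxidative phosphorylation members, 1 was higher and 1 lower than in CD4-like cells in library 1 alone and 4 and 1 in library 2 alone. Of glycolysis genes, 2 of 13 were higher than in CD4-like cells, and 3 of 14 were higher and 1 lower than in CD8-like cells. Hk2, the gene of the first enzyme of glycolysis, was 12.99-fold (6.24 to 31.3) and 63.8-fold (17.01 to 537) higher, at 309 CPM in MAIT-like, 23.8 in CD4-like and 4.84 in CD8-like cells. Pfkp was 2.32-fold (1.10 to 5.07) and 1.85-fold (0.944 to 3.62) higher, Pkm 1.81-fold above CD8-like cells (1.37 to 2.40), and Slc2a3, a glucose transporter gene, 2.34-fold below them (0.644 to 12.8) on 13 UMIs. Slc2a3 was at −0.82 and −0.028 log2 within libraries 1 and 2. Glycolysis members higher than in CD4-like cells were 1 of 11 in library 1 alone and 5 of 12 in library 2 alone. The glycolysis medians were 0.25 and 0.22 log2, at the 86.6 and 80.8 percentiles, and the oxidative phosphorylation median over CD8-like cells was 0.17 within library 1, −0.19 within library 2 and −0.15 with TMM scaling. The glycolysis median over CD4-like cells was −0.16 with UMIs thinned to 1000 per cell. Hk2 was 3.74-fold (1.13 to 14.2) and 3.06-fold (1.21 to 7.18) higher with gates, and −0.21 log2 against the CD8 gate within library 1.

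**Figure D3:**
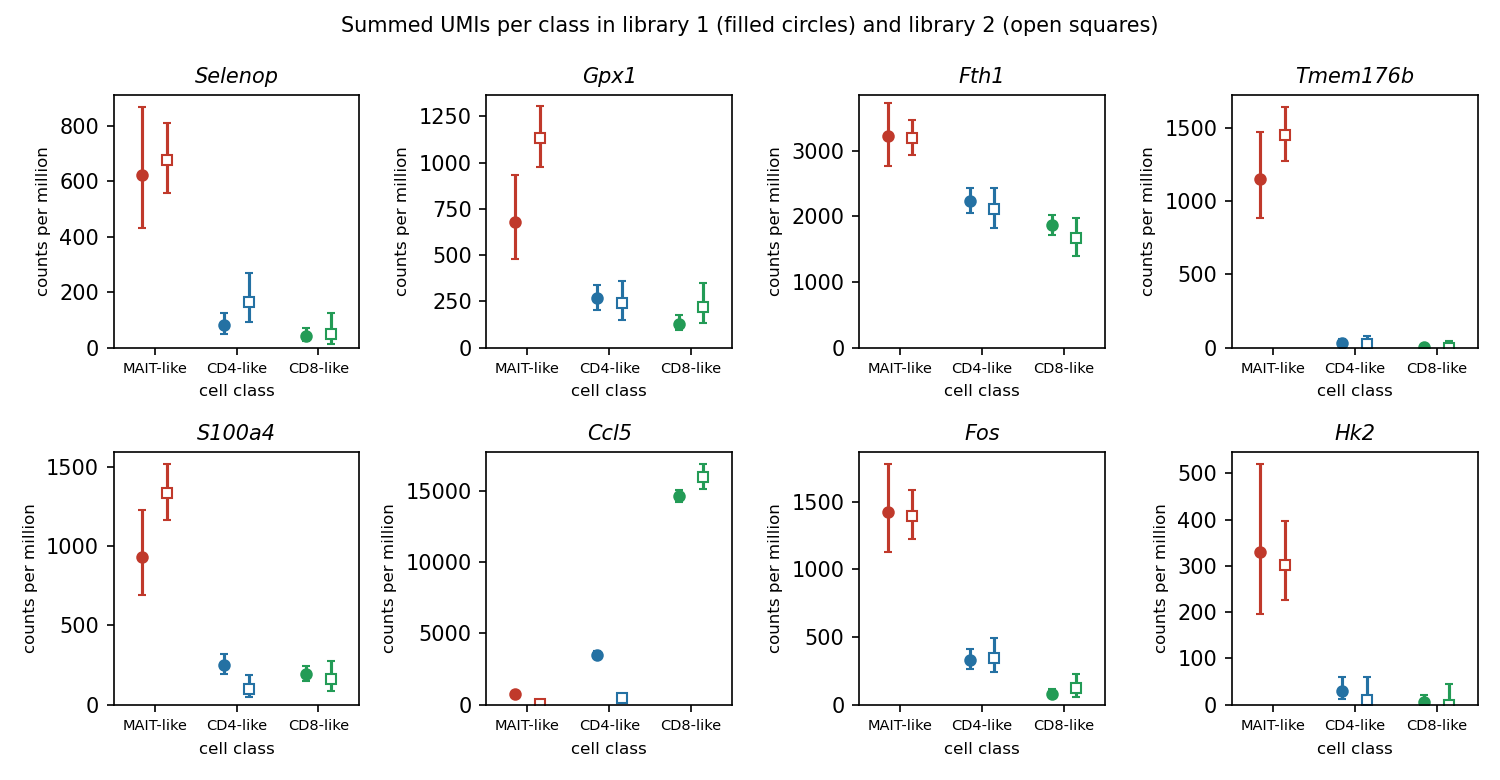
CPM of summed UMIs of Selenop, Gpx1, Fth1, Tmem176b, S100a4, Ccl5, Fos and Hk2 in MAIT-like, CD4-like and CD8-like cells; filled circles are library 1, open squares library 2, and error bars exact 95% Poisson intervals. Selenop was at 622 and 676 CPM in MAIT-like cells of libraries 1 and 2 and at 81.8 and 163 CPM in CD4-like cells.

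Genes outside the lists were compared between 26 cells of the MAIT gate, 68 of the CD4 gate and 174 of the CD8 gate. By class the MAIT gate held 20 MAIT-like, 5 CD8-like and 1 unnamed cell. The CD4 gate held 42 CD4-like, 5 CD8-like, 2 MAIT-like and 19 unnamed cells. Ckb, the brain-type creatine kinase gene, was 13.8-fold above the CD4 gate (6.51 to 33.6) and 19.1-fold above the CD8 gate (10.9 to 35.2), with a UMI in 76.9%, 7.35% and 6.90% of cells. Rgcc, a cell cycle regulator gene, was 11.03-fold (5.55 to 24.3) and 10.2-fold (6.42 to 16.3) higher, the transcriptional co-regulator gene Lmo4 6.56-fold (3.45 to 13.4) and 13.2-fold (7.50 to 24.1), and the adhesion gene Jaml 20.1-fold (6.23 to 103) and 5.23-fold (3.07 to 8.84). The others of the 10 highest were Clcn3, Anapc13, Hadhb, F2r, Smox and Acd, and the smaller of their log2 folds lay between 2.05 and 2.32. Between the classes, over CD4-like and CD8-like cells, Hadhb was at 0.90 and 0.99 log2, Anapc13 at 1.32 and 1.08 and Acd at 1.85 and 1.21. Clcn3 was at 1.73 and 2.63, F2r at 3.95 and 1.98 and Smox at 3.27 and 4.66. Among the lowest, Cd6, Klf3, Cd27 and Malt1 had no UMI in the MAIT gate. Cd6 and Cd27, both T cell costimulatory genes, were at least 5.45-fold and 2.88-fold below the CD4 gate and at least 2.94-fold and 3.86-fold below the CD8 gate. Selenop was 4.85-fold (2.86 to 8.52) and 10.4-fold (6.41 to 16.99) higher with these gates, and Gpx1 3.68-fold (2.497 to 5.476) and 6.21-fold (4.45 to 8.66). Within libraries 1 and 2 Selenop was at 1.52 and 1.77 log2 over the CD4 gate (2.21 pooled) and 2.30 and 3.09 over the CD8 gate (3.30 pooled), and Gpx1 at 0.68 and 1.97 and at 1.52 and 2.32.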

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

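The thinning tests of Selenop and of the immediate early genes were set before their results were seen. All other tests here were chosen after the result was seen.

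The smooth muscle gene Acta2, a signal in cells outside the compared classes, had 276 UMIs in cluster 3, in 3 of its 41 cells. The complement gene C1qa, a signal of the same kind, had 46 UMIs in cluster 7, in 6 of its 15 cells. The haemoglobin gene Hbb-bs, outside the compared cells, had 4444 UMIs over all barcodes, of which 4441 lay in 1 barcode of library 1 with 132 genes that was not kept.

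The MAIT-like share was 5.70% in library 1 and 31.0% in library 2, although the labels describe parts of 1 mixture. Chance in dividing the mixture is argued against by a gap of 15.5 percentage points between the intervals, and depth by a gap of 8.96 points in the share with a Cd8a or Cd8b1 UMI at 1000 UMIs per cell. The cell filter and doublet calls are argued against by a gap of 17.1 points in the same share over all barcodes. That the libraries held different mixtures cannot be told apart from other steps before sequencing, because no record of loading was analysed here; MAIT-like cells were 41.7% of the named classes in library 2. No biological explanation was tested, since the labels give 1 group.

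Selenop was higher in MAIT-like cells in both comparisons. RNA or doublets from macrophage-like cells would need the abundant genes of cluster 7. Of Apoe, C1qa, C1qb, Cd74 and Lyz2, tested for this, the largest upper 95% limit of the UMIs in MAIT-like cells was 0.721% of the UMIs needed. For Apoe, Igfbp7, Mgp and Acta2 of cluster 3, which held stromal genes, the largest such limit was 6.42%. Cd3 genes of T cells had a UMI in 68.3% of cells of cluster 3 and 80% of those of cluster 7. The ratios to Selenop are therefore not those of stromal or macrophage cells alone. The UMIs needed rest on 9 Selenop UMIs in cluster 7, where 1 cell held 73.9% of the C1qa and 98.1% of the Cd74 UMIs. In cluster 3, 1 cell held 50.3% of the Mgp UMIs. The limits leave out the error of these ratios. Cells rich in these genes tend to be placed in clusters 3 and 7, and called doublets were removed. These counts therefore cannot test doublets, and they test free RNA only for a source with these ratios. A difference between the libraries is argued against by the smallest fold within a library, 2.00 log2, and depth by a share of cells with a UMI 46.0 percentage points above the other classes at 1000 UMIs per cell. Transcription of Selenop in the MAIT-like cells themselves may account for it, as a hypothesis found and tested on the same data. Sources outside these 2 clusters were not tested.

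Immediate early genes were higher in MAIT-like cells. A difference between the libraries as the whole of this is argued against by a smallest median of 1.18 log2 within a library over the same members. With members chosen again in library 1 it was 1.09. The pooled medians of 1.77 and 2.80 lay above those within either library, and were 1.07 and 2.30 with libraries weighted equally. The pooled sizes are therefore not free of the uneven division of classes between libraries. Depth is argued against by a median of 1.44 at 1000 UMIs per cell. Handling during separate sorting cannot be told apart from a property of MAIT cells, since each sorted population has 1 handling, and the smaller median with gates, 1.06, fits either.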

How the results depend on the processing

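Alternatives added after the data were seen are the equal weighting of libraries, the unnamed clusters added to classes, the cell with the most UMIs left out, and the counts of list members by library, scaling and gate. Depth limits genes with few UMIs. Of 106 log2 folds of named list genes, 8 reversed with gates, 10 with the stricter MAIT gate of 4 cells, 6 with the stricter cell filter, 3 with called doublets kept, 2 at resolution 2.0, 1 with UMIs thinned and 0 with unnamed clusters added. TMM scaling shifts all genes of a comparison alike and most named genes were chosen for a large fold, so its 0 reversals say little. A value counts as reversed only if it was called, which for a list median means outside the central 95% of random lists. Values within the limit of change are counted as stable even where a value near 0 changed sign. Over all alternatives 1177 folds of list genes were stable, 171 moved and 30 reversed, with a change of sign in 18 of the stable and 1 of the moved folds. Of the list medians 232 were stable, 150 moved and 8 reversed, with a change of sign in 8 of the stable and 9 of the moved medians, so 25 changed sign in all. Of the genes named by gates 94 were stable and 26 moved, none with a change of sign. Type 17 medians stayed positive and naive medians negative under every alternative that gave a value, and type 17 members past the rule numbered 8 to 11 higher and at most 1 lower by library, TMM scaling and gate. Resolution 0.5 and list members included in the clustering gave no MAIT-like class, so no fold could be computed there. The cause was not tested for any value that moved or reversed. Gates and classes held partly different cells, and most Ccl5 UMIs of the MAIT gate lay outside the MAIT-like class. All 65 Il17a UMIs of the CD4 gate lay in 1 MAIT-like cell. Class shares and list medians that moved or reversed and genes that reversed are given next, as percentages of kept cells or log2 folds, while the 171 folds of list genes and 26 of genes named by gates that moved are given as counts only.

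With the stricter cell filter, class shares were CD8-like 22.8%. With the stricter cell filter, medians over CD4-like cells were type 1 −1.06, naive −3.32, immediate early 2.40 and interferon 0.29. With the stricter cell filter, medians over CD8-like cells were antioxidant 0.51, innate-like 1.75, regulatory 2.53, repair 1.66, immediate early 3.12, interferon −0.86 and glycolysis 0.54. With the stricter cell filter, genes reversed over CD4-like cells were Bst2 0.32 and Usp18 0.64. With the stricter cell filter, genes reversed over CD8-like cells were Ifit1 −1.29, Ifit3 −1.66, Irf7 −0.75 and Tnfrsf9 −0.056. With called doublets kept, medians over CD4-like cells were type 1 −0.37, naive −2.07, immediate early 1.45, interferon −0.38 and glycolysis 0.031. With called doublets kept, medians over CD8-like cells were antioxidant 0.28, naive −0.81, regulatory 1.55, repair 1.56, immediate early 2.57 and interferon −0.73. With called doublets kept, genes reversed over CD8-like cells were Ifit1 −1.49, Ifit3 −2.50 and Irf7 −0.44. With resolution 0.5, class shares were CD8-like 45.6%. With resolution 2.0, class shares were CD4-like 20.1%. With resolution 2.0, medians over CD4-like cells were type 1 −0.38, immediate early 1.49, interferon −0.14 and glycolysis 0.058. With resolution 2.0, medians over CD8-like cells were repair 0.77, immediate early 3.06 and interferon −0.40. With resolution 2.0, genes reversed over CD8-like cells were Ifit1 −0.54 and Ifit3 −0.90. With list members included in the clustering, class shares were CD8-like 37.7%. With gates, class shares were MAIT-like 4.98%, CD4-like 13.03% and CD8-like 33.3%. With gates, medians over CD4-like cells were type 17 2.63, type 1 0.56, innate-like 1.29, naive −3.13, regulatory 0.80, inhibitory −0.12, immediate early 1.06 and interferon 0.35. With gates, medians over CD8-like cells were antioxidant 0.45, type 17 4.10, type 1 −1.30, innate-like 1.28, naive −2.82, repair 0.85, inhibitory −2.10, immediate early 1.76, interferon −0.51 and glycolysis 0.52. With gates, genes reversed over CD4-like cells were Bst2 1.08, Ccl5 0.057, Il17a −1.33 and Nr4a2 0.54. With gates, genes reversed over CD8-like cells were Cd160 0.28, Ifit1 −0.51, Ifit3 −1.03 and Satb1 −3.19. With the stricter MAIT gate, class shares were MAIT-like 0.766%, CD4-like 13.03% and CD8-like 33.3%. With the stricter MAIT gate, medians over CD4-like cells were antioxidant −0.036, type 17 2.13, type 1 0.61, naive −2.80, residency 0.92, regulatory 0.99, repair 0.83, immediate early 1.89, interferon −0.48, oxidative phosphorylation 0.36 and glycolysis −0.13. With the stricter MAIT gate, medians over CD8-like cells were type 17 3.35, type 1 −1.56, innate-like 1.63, naive −3.33, repair 0.70, inhibitory −3.39, immediate early 2.69, interferon −1.10 and glycolysis 0.93. With the stricter MAIT gate, genes reversed over CD4-like cells were Bst2 0.65, Cox5a −0.34, Hspa1b −1.39, Il17a −2.24, Nr4a2 0.14 and Tnfrsf18 0.46. With the stricter MAIT gate, genes reversed over CD8-like cells were Cd160 1.40, Ifit1 −4.82, Ifit3 −4.79 and Satb1 −3.03. With TMM scaling, medians over CD4-like cells were type 1 −0.65, immediate early 1.66 and interferon −0.79. With TMM scaling, medians over CD8-like cells were antioxidant 0.028, innate-like 0.96, immediate early 2.63, interferon 0.35 and glycolysis 0.051. With UMIs thinned to 1000 per cell, medians over CD4-like cells were type 1 −0.36, naive −2.61, inhibitory −2.68, immediate early 1.44, interferon −0.51 and glycolysis −0.16. With UMIs thinned to 1000 per cell, medians over CD8-like cells were innate-like 1.41, repair 1.62, inhibitory −1.72, immediate early 2.23 and interferon 0.36. With UMIs thinned to 1000 per cell, genes reversed over CD8-like cells were Satb1 −0.43. With cells with a macrophage UMI left out, medians over CD4-like cells were immediate early 1.78. With cells with a macrophage UMI left out, medians over CD8-like cells were immediate early 2.61 and interferon 0.58. With no minimum of UMIs, medians over CD4-like cells were naive −2.11 and regulatory −1.98. With no minimum of UMIs, medians over CD8-like cells were repair 0.25. With a minimum of 50 UMIs, medians over CD4-like cells were type 17 5.23, type 1 −0.38, innate-like 1.39, naive −2.89 and immediate early 1.40. With a minimum of 50 UMIs, medians over CD8-like cells were antioxidant 0.39, type 17 6.43, innate-like 1.27, repair 0.74 and immediate early 2.64. With a pseudocount of 5 UMIs, medians over CD4-like cells were type 17 2.81, innate-like 1.28, naive −1.53, immediate early 1.69 and interferon −0.62. With a pseudocount of 5 UMIs, medians over CD8-like cells were type 17 3.30, innate-like 1.03, regulatory 1.37, immediate early 2.47 and interferon 0.48. With libraries weighted equally, medians over CD4-like cells were type 17 3.50, type 1 −0.16, naive −2.80, immediate early 1.07 and interferon −0.53. With libraries weighted equally, medians over CD8-like cells were type 17 3.88, regulatory 1.14, immediate early 2.30 and interferon 0.61. With unnamed T-cell clusters added to classes, class shares were CD4-like 33.5% and CD8-like 41.8%. With unnamed T-cell clusters added to classes, medians over CD4-like cells were type 1 −0.97, immediate early 1.76 and interferon −0.44. With unnamed T-cell clusters added to classes, medians over CD8-like cells were naive −1.91, immediate early 2.72, interferon 0.29 and glycolysis 0.34. Leaving out each library in turn, with members chosen again in the other, gave shares of MAIT-like 5.70% to 31.0% and CD8-like 17.5% to 31.1%. The same step gave medians over CD4-like cells of antioxidant 0.21 to 0.44, type 17 3.56 to 4.39, type 1 0.0027 to 0.41, innate-like 1.17 to 1.87, naive −2.83 to −2.57, regulatory −1.55 to −0.21, repair −0.24 to 0.36, inhibitory −0.67 to −0.32, immediate early 1.09 to 1.18, interferon −0.38 to −0.32 and oxidative phosphorylation 0.086 to 0.26. It gave medians over CD8-like cells of antioxidant 0.33 to 0.51, type 17 4.61 to 6.08, type 1 −3.13 to −1.70, innate-like 1.23 to 1.25, regulatory 0.82 to 1.85, repair 0.44 to 2.27, inhibitory −1.57 to −0.96, immediate early 2.13 to 2.18, interferon 0.58 to 0.58 and glycolysis 0.22 to 0.34.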

Other observations

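The test of beta segments below was chosen after the data were seen. Cells outside the compared classes held several groups. Cluster 3, of 41 cells with a median of 5471 UMIs, had the smooth muscle gene Tagln in 5 cells, the matrix gene Mgp in 10 and the cycling gene Top2a in 7, beside Cd3e of T cells in 28. Cluster 7, of 15 cells with a median of 757 UMIs, had the complement gene C1qb in 7 cells and Apoe in 5, beside Cd3e in 7. All its cells came from library 1, and no cell of library 2 fell in it. Clusters 4 and 6, of 79 and 34 cells, had Cd3 genes in 94.9% and 94.1% of cells and met no naming rule.

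Marker scores of the MAIT-like cluster, as mean log2 ratios to the other cells, were 1.34 for MAIT, 0.51 for gamma delta T cells, −0.093 for T cells, −0.36 for CD4 and −1.85 for CD8 markers. They were −0.24 for natural killer and innate lymphoid, −0.44 for macrophage, −1.03 for antigen-presenting, −0.11 for B cell, −0.39 for fibroblast, −0.30 for endothelial, −0.029 for erythroid and −0.47 for cycling markers. Invariant natural killer T cell and neutrophil markers scored 0. Selenop had a UMI in 10.9% of the cells of CD4-like cluster 1 and in 23.4% of those of CD4-like cluster 5.

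A hypothesis was that cells of the MAIT-like cluster also use the beta segments known from MAIT receptors. Trbv13 or Trbv19 was found in 69.7% of MAIT-like cells with a Trbv UMI (57.2 to 80.4, 46 of 66), 36.8% of CD4-like cells (46 of 125) and 42.7% of CD8-like cells (56 of 131). The gap to the higher of the other classes was 26.9 percentage points for the segments together, but they differed. Trbv13-3 was found in 25.8% of MAIT-like cells (15.8 to 38.01), 5.60% of CD4-like and 9.16% of CD8-like cells (4.82 to 15.45), with intervals that do not overlap. For Trbv13-2, at 31.8% (20.9 to 44.4), 17.6% (11.4 to 25.4) and 23.7% (16.7 to 31.9), and Trbv19, at 16.7% (8.63 to 27.9), 9.60% (5.06 to 16.2) and 9.16%, the intervals overlap. Trbv13-1 went the other way, with 0 of 66 MAIT-like cells, which allows a share of up to 4.545%, against 7.20% and 6.87%. The hypothesis thus holds for the set as a whole and not for each segment. Trav1, which is among the markers that named the class, was found in 54.1% of MAIT-like cells with a Trav UMI (20 of 37), in 5.68% of CD8-like cells (5 of 88) and in 0 of 92 CD4-like cells, which allows a share of up to 3.26%.

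A few cells held much of some genes. The library 1 cell with 65 of the 97 Il17a UMIs also held 18 of the 21 Il17f UMIs. Another library 1 cell held all 11 Trdv4 and all 6 Cd163l1 UMIs of the MAIT-like class and 9 Selenop UMIs; Trdv4 encodes a gamma delta receptor segment.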
